A study of Homo sapiens with 39 samples.

How the data were processed

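The series holds 39 human samples from 3 assays. Polysome gradients of human bronchial epithelial cells (HBEC) gave 24 RNA-seq libraries, 8 per line, from monosomes, from fractions holding 2 to 7 ribosomes and from a pooled fraction holding 8 to 10, in a wild-type line (WT), a line with the U2AF1 S34F mutation and a line labelled Frame Shift (FS). RNA immunoprecipitation (RIP-seq) of U2AF1 in the same 3 lines gave 9 libraries, 1 each of U2AF1 precipitate (IP), control immunoglobulin precipitate (IgG) and cytosolic RNA (Cytosol) per line. PAR-CLIP, which marks the contacts of a protein on RNA by T-to-C conversions, was done in Flp-In-293 cells, a HEK 293 derivative, that expressed FLAG-HA tagged U2AF1. It covered WT protein in cytoplasm, S34F protein in cytoplasm and WT protein in chromatin, with 2 replicates each, which are pooled in the 3 deposited cluster lists per the series design text. RNA of the gradients was extracted with TRIzol and made into libraries with the NEBNext Ultra II kit, per the labels' protocols. The labels do not say which allele carries the frame shift of the FS line.

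The polysome table and the RIP tables hold expected counts per gene symbol as the authors deposited them, per the file headers, since 57.4% of polysome values and 26.3% of RIP values were not whole numbers. TopHat is the only tool that the submitters' processing notes name, without a version. The counting tool, its annotation, any use of strand and the genome build are not stated in the headers or labels. The RPKM column deposited by the authors in the RIP tables was used only for a check: its library total, the same for every gene of a table, was 3.15 to 5.68 times the summed counts. The PAR-CLIP lists hold whole-number counts of reads and conversions per cluster and a T-to-C fraction per cluster, deposited by the authors per the file headers. The cluster caller is not stated, and the annotation source column of the lists names HAVANA and ENSEMBL. Every cluster held at least 2 conversion positions and at least 4 reads. Cluster positions are given as in the lists, whose genome build is not stated.

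The polysome table had 21603 entries, of which 28 carried gene names turned into dates. For a symbol listed more than once, extra entries were dropped, 45 in the polysome table and 119 in the RIP table, which left 21530 and 26334 symbols. Total counts ran from 2440110 to 13367474 per polysome library and from 2582162 to 29769920 per RIP library. A count of 0 allows up to 3 counts, which is 0.224 to 1.23 CPM (counts scaled to the same total in each library) in the polysome libraries and 0.101 to 1.16 CPM in the RIP libraries. These limits and the intervals of shares cover counting error only. Intervals of medians over genes came from 2000 bootstrap draws of the genes. They treat genes as independent and do not cover the spread between samples. Genes listed at 0 in at least 1 library and at 50 CPM or more in another numbered 78 in the RIP table and 122 in the polysome table. Such isolated zeros came with the deposited counts, and fits without these genes were added as an alternative.

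Tested comparisons used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3 on the counts rounded to whole numbers, with filterByExpr, TMM scaling and the quasi-likelihood test, at a Benjamini-Hochberg adjusted p under 0.05. The RIP fit took all 9 libraries, kept 11612 genes and compared IP with IgG, IP with Cytosol and IgG with Cytosol. The polysome fit took all 24 libraries, kept 15945 genes and compared the 8-10 fraction with monosomes. Line was a block in both fits. The pairing comes from the shared cell line, since the 3 lines are the only replication. Deviations from the group means of libraries from the same line correlated at a median r of 0.079 across genes in RIP (0.037 to 0.156, above 0 in 9 of 9 pairs) and of 0.423 in the polysome libraries (-0.301 to 0.783, above 0 in 77 of 84 pairs). Libraries of other lines had -0.041 and -0.23. Deviations of 3 lines sum to 0, so these negative values follow from the others and are no separate evidence. The p-values measure only the spread between these samples, in which genotype differences are part of the residual. The common dispersion was 0.487 in RIP, a biological coefficient of variation of 69.8%, and 0.108 in the polysome libraries, or 32.9%. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists tested.

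Between lines there is 1 library per line and kind, so no test was run and no replicate check exists for any difference between lines. Ribosome number was the CPM-weighted mean over the 8 fractions, with 9 for the 8-10 fraction, for 9504 genes with at least 500 counts in each gradient. CPM gives every fraction the same total, so the RNA amount per fraction is lost. The number is thus a relative index of position in the gradient, not a count of ribosomes carried. A gene stood apart in a line when it differed from both other lines by at least 0.5 ribosomes the same way. RNA level was compared as log2 CPM with a prior of 1 CPM, in Cytosol and in the mean of the 8 fractions, and a gene counted as different at 2-fold or more in both sets with all 8 fractions in that direction and at least 50 Cytosol counts in 1 of the lines compared. IP enrichment was log2 of IP over Cytosol CPM per line, with a prior of 1 CPM and at least 50 counts in IP or Cytosol of each line. For these differences and for PAR-CLIP targets, the median of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Random lists draw unrelated genes, while members of a list can move together, so these percentiles can overstate how unusual a list is. Cluster lists were overlapped with bedtools 2.31.1 by at least 1 nt on the same strand, and overlaps after a shift of 500 nt served as background. Shares of clusters carry Wilson 95% intervals. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the alternatives used DESeq2 1.42.0.

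The tests, filters, gene lists and the rule for named genes were fixed before the data were examined. In tested comparisons the rule took the 10 highest and 10 lowest fold changes among called genes with a named symbol, a mean of at least 10 CPM and the same direction in all 3 lines. Between lines it took the 8 highest and 8 lowest that met the size rule, ranked by the smaller difference (ribosome number, at least 1000 counts per gradient), the smaller fold (RNA level) or the S34F minus WT difference (IP enrichment, at least 200 Cytosol counts). It also took the 8 genes with most cluster reads per PAR-CLIP list, the 4 most abundant members of each gene list, and always U2AF1, U2AF2, NPM1, CXCL8, GAPDH, ACTB, MALAT1 and NEAT1. Other called list members are named as well, a choice made after their values were seen. The 24 lists covered ribosomal proteins, translation factors, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, replication-dependent histones, nuclear-retained noncoding RNAs, snoRNA host genes, upstream-ORF and integrated stress response genes, inflammatory and chemokine genes, 3-prime splice site recognition and core splicing, basal airway epithelium, squamous differentiation, mesenchymal genes, secretory and ciliated airway cells, leukocyte and endothelial cells, p53 targets, interferon response, cell cycle, heat shock and chaperones, glycolysis and hypoxia, cholesterol synthesis, the proteasome, extracellular and membrane proteins made at the endoplasmic reticulum (ER), and genes with exon use described for U2AF1 S34F. Transcript lengths were those of the RIP tables.

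The fits were tested on simulated counts drawn from each gene's share of all counts and its fitted dispersion, with 200 genes changed. For IP against IgG over 11612 genes, 3% of 2-fold and 36% of 4-fold changes were recovered, with 1 false call among 40. For 8-10 against monosomes over 15945 genes, 13% and 93% were recovered, with 8 false calls among 114. Shifts simulated on the WT gradient with counting error only were recovered for 198 of 198 genes over 9856 genes, with 0 unchanged genes past the threshold. Alternatives covered other scalings, DESeq2, filters, the block, samples in the fit, each line left out, priors, count minimums, fractions, references, cluster thresholds and overlaps. Reads were not realigned, and splicing was not analysed here.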

Results

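RNA bound by U2AF1, a subunit of the factor that recognizes the 3-prime splice site, was compared with control precipitate and cytosolic RNA in 3 HBEC lines, and ribosome loading was followed over 8 gradient fractions of the same lines. The RIP libraries held 8553113, 3549144 and 8837187 counts in WT IP, IgG and Cytosol, 2582162, 4588807 and 14014497 in S34F, and 3067140, 2962979 and 29769920 in FS. Polysome libraries held 2440110 to 10927158 counts in WT, 4954030 to 10422583 in S34F and 3292289 to 13367474 in FS. U2AF1 mRNA itself stood at 53.9 CPM in WT Cytosol, 21.5 in S34F Cytosol and 54.7 in FS Cytosol. In IP it stood at 46.2, 5.0 and 27.7 CPM and in IgG at 50.4, 4.4 and 10.5 CPM for WT, S34F and FS. Its mean over the polysome fractions was 44.2 CPM in WT (20.2 to 91.3), 24.3 in S34F (12.8 to 40.7) and 57.8 in FS (15.2 to 102). The S34F line thus held the lowest U2AF1 level in every kind of RIP library and in the polysome mean.

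Single mRNAs of translation factors and ribosomal proteins were higher in U2AF1 IP than in IgG, 3 of 41 and 9 of 77, while 13 of 47 mRNAs of extracellular and membrane proteins were lower. These lists were called by camera at its preset correlation but not with an estimated one (adjusted p = 0.595, 0.718 and 0.718 with an estimated correlation). EEF1A1, the elongation factor that brings aminoacyl-tRNA to the ribosome, rose by 0.92±0.11 log2 (adjusted p = 5.7e-04) and the ribosomal stalk protein gene RPLP0 by 0.79±0.12 (adjusted p = 0.00283). COL4A2, a basement membrane collagen chain, fell by 4.07±0.51 (adjusted p = 0.00100), and the amino acid transporter subunit SLC3A2 fell by 1.70±0.21 (adjusted p = 8.9e-04). By edgeR's quasi-likelihood test with BH adjustment, 26 genes were higher and 130 lower in IP among 11612, 13 and 118 of them at least 2-fold, and all 156 kept their direction in the 3 lines. The largest increases were in the co-chaperone DNAJA2 (2.97±0.61, adjusted p = 0.0237), the nucleotide synthesis enzyme PRPS2 (2.64±0.61, 0.0423), the actin-severing protein DSTN (1.62±0.39, 0.0489), the small GTPase CDC42 (1.5±0.32, 0.0258) and the kinase HIPK3 (1.49±0.29, 0.0180). DNAJA2 and PRPS2 had low IgG levels, at 9.3, 8.3 and 1.7 CPM and at 5.9, 4.8 and 10.5 CPM in WT, S34F and FS. CDC42 stood at 113.5, 104.6 and 103.4 CPM in IP, near its Cytosol level of 99.6, 104.9 and 95.5 CPM. In IgG it stood at 34.1, 34.9 and 31.7 CPM, so its increase lay in a low IgG level. Next came the initiation factor subunit EIF2S3 (1.438±0.31, 0.0281), the repair and proteasome shuttle factor RAD23B (1.41±0.32, 0.0352), the corepressor CTBP2 (1.40±0.32, 0.0367), SCRN1 (1.27±0.26, 0.0209) and the RNA-binding protein HNRNPF (1.21±0.28, 0.0381). The largest decreases beside COL4A2 were in the transporter ABCC3 (-4.44±0.86, adjusted p = 0.0171), COL4A1 (-3.76±0.81, 0.0286), the lysosomal PLBD2 (-3.64±0.68, 0.0144), the tumour suppressor RASSF1 (-3.26±0.65, 0.0206), the membrane protein CLSTN3 (-2.92±0.57, 0.0180) and the matrix protein TNC (-2.48±0.49, 0.0194). MIR6723 (-4.99±0.92), KRT18P55 (-3.32±0.75) and SCARNA12 (-2.56±0.42) also fell, but their reads are shared with near-identical copies or a host gene, so their assignment is uncertain. U2AF1 (0.25±0.60, adjusted p = 0.908), U2AF2 (-0.47±0.25, 0.469), NPM1 (0.71±0.21, 0.136), GAPDH (0.10±0.11, 0.760), ACTB (-0.02±0.12, 0.977), MALAT1 (-0.28±0.20, 0.617) and NEAT1 (-0.84±0.26, 0.152) were not called, and CXCL8 was not tested in RIP.

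As a group, the mRNAs of extracellular and membrane proteins made at the ER had a median of -1.08 in IP against IgG, with 0 of 47 members above 0. By camera the list had an adjusted p of 9.0e-15, and an adjusted p = 0.718 with an estimated correlation. Called members included the integrins ITGA3 (-1.436) and ITGB4 (-1.501), the laminin chains LAMA3 (-1.37) and LAMB3 (-1.67), fibronectin FN1 (-1.69), TGFBI (-0.90), the lysosomal genes LAMP1 (-1.30), PSAP (-1.64), GRN (-1.90) and CTSD (-1.68), and the amino acid transporter pair SLC7A5 (-1.04) and SLC3A2. The basal airway list, with a median of -0.57, had a camera adjusted p of 5.0e-04 and an adjusted p = 0.595 with an estimated correlation. It held 7 lower members of 28, with keratin KRT5 (-0.58) and the hemidesmosome collagen COL17A1 (-1.45) beside the integrins and laminins. Ribosomal protein mRNAs had a median of 0.33 and 9 higher members of 77 (camera adjusted p = 2.5e-04; adjusted p = 0.718 with an estimated correlation). These included RPL3 (0.71), RPL5 (0.98), RPL6 (0.70), RPLP0, RPS3 (0.55), RPS3A (0.89), RPS6 (0.97) and RPS16 (0.65), while RPS2 (0.19) and RPL8 (0.13) were not called. Translation factors had a median of 0.34, with EEF1A1, EIF2S3 and EIF3F (0.81) higher among 41 (camera adjusted p = 0.00770; adjusted p = 0.595 with an estimated correlation). After a trend on transcript length was removed, medians were 0.176 for translation factors, 0.306 for ribosomal proteins and -1.196 for the ER list. Adjusted over the list alone, called members numbered 32 for the ER list, 13 for the basal list, 24 for ribosomal proteins and 11 for translation factors. Genes in lists not called included the chaperones HSPA5 (-1.36) and PDIA4 (-1.25), the sterol enzymes LSS (-1.34) and DHCR7 (-1.53), the glucose transporter SLC2A1 (-1.45) and the noncoding RNAs FTX (1.06) and RMRP (-1.02). HLA-C (-1.28) was lower too, with reads that related genes can share. The 22 histone genes measured had a median of 0.18 with 0 called (camera adjusted p = 0.289), and no mitochondrially encoded mRNA was in any table. Squamous (median -0.95, mean -0.36, test up), p53 (-0.09, 0.07, down) and proteasome lists (-0.17, 0.20, down) differed in sign between their median, mean or test. DESeq2 called 667 genes, of which 33.9% were higher against 16.7% here, and without the line block 0 genes were higher and 32 lower. Leaving out WT left 2 higher and 15 lower genes, leaving out FS 10 and 77, and leaving out S34F 20 and 187.

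Against Cytosol, 12 of 77 ribosomal protein mRNAs and 2 of 12 nuclear noncoding RNAs were higher in U2AF1 IP, in lists that camera did not call with an estimated correlation (adjusted p = 0.545 for both). NEAT1 and MALAT1 were higher still in IgG over Cytosol, at 2.95 and 1.52 log2. RPS6, a 40S subunit protein gene, rose by 1.25±0.16 log2 (adjusted p = 3.6e-04), EEF1A1 by 0.74±0.11 (0.00101), NEAT1, the RNA scaffold of paraspeckles, by 2.11±0.26 (2.0e-04) and MALAT1 by 1.23±0.20 (0.00419). The Argonaute gene AGO2 rose by 4.08±0.63 (adjusted p = 0.00245), with 344 CPM in IP against 169 CPM in Cytosol in WT, 1620 against 51.2 in S34F and 1486 against 56.1 in FS. AGO2 was not among the 10 largest increases in IP over IgG, but its own values with IgG are not given here. Its fold over Cytosol alone does not separate U2AF1 binding from background. By edgeR's quasi-likelihood test 57 genes were higher and 5 lower in IP than in Cytosol, 45 and 1 at least 2-fold, and 62 of 62 kept their direction in each line. Other large folds were in the potassium channels KCNK10 (3.32±0.66) and KCNJ10 (3.18±0.33), the myelin gene MOBP (3.24±0.33), the integrin ITGA11 (3.20±0.26, adjusted p = 2.1e-06), the receptors GFRA1 (3.20±0.34), TREML2 (3.19±0.32) and MC2R (3.17±0.32), and the corepressor RUNX1T1 (3.19±0.29). These 8 belong to a set of 33 genes that were higher still in IgG, with a median IP over IgG of -1.12. Reads of this set may come from a shared source, as set out below. KRT19, a simple-epithelium keratin, was listed at 0 in all 3 Cytosol libraries and at 1054, 1494 and 979 CPM in IP of WT, S34F and FS, so its fold has no defined size. Lower genes included COL4A2 (-2.92±0.49, adjusted p = 0.00563), the caveolar PTRF (-0.79±0.16), and the cytoskeletal linkers PLEC (-0.71±0.13) and FLNA (-0.70±0.12). U2AF1 (-1.19±0.60, adjusted p = 0.704), U2AF2 (-0.53±0.25, 0.680), NPM1 (0.42±0.21, 0.696), GAPDH (-0.11±0.11, 0.902) and ACTB (-0.29±0.12, 0.584) were not called. The ER list had a median of -0.22 and 0 of 47 members called (camera adjusted p = 0.298). Among 77 ribosomal proteins 12 were higher, with a median of 0.37 (camera adjusted p = 6.2e-12; adjusted p = 0.545 with an estimated correlation). Beside RPS6 these included RPL5 (0.96), RPL6 (1.08), RPL7A (0.94), RPL10A (0.88), RPLP0 (0.69), RPSA (0.64), RPS3 (0.62), RPS3A (0.97), RPS16 (0.70) and RPS20 (0.66). Translation factors had a median of 0.19 (camera adjusted p = 0.0417; adjusted p = 0.545 with an estimated correlation), with EIF3L (1.04) called beside EEF1A1. The nuclear noncoding list had a median of 0.74 (camera adjusted p = 0.0112; adjusted p = 0.545 with an estimated correlation) and the snoRNA hosts 0.40 (0.0417; adjusted p = 0.545 with an estimated correlation). Glycolysis (-0.46, camera adjusted p = 0.0417; adjusted p = 0.611 with an estimated correlation) and proteasome mRNAs (-0.47, 0.0417; adjusted p = 0.568 with an estimated correlation) were lower as lists. Over the list alone, 34 ribosomal proteins, 4 translation factors, 4 nuclear RNAs and 3 snoRNA hosts were higher. The basal list (median -0.20, mean 0.68, test down), the exon-use list (0.19, -0.02, up) and the chaperones (-0.01, 0.06, up) differed in sign. DESeq2 called 115 higher and 52 lower, a higher share of 68.9% against 91.9%, and the fit without the block called 36 higher and 0 lower. The lower count was 1 without FS and 2 without WT.

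IgG held more of the same secreted and membrane protein mRNAs than Cytosol did. Among 47 members of the ER list 9 were higher, with a median of 0.95 (camera adjusted p = 1.8e-17; adjusted p = 0.442 with an estimated correlation). They were NOTCH2 (1.61), FN1 (1.41), GRN (1.31), PSAP (1.29), SLC3A2 (1.23), ITGB4 (1.16), ITGA3 (1.04), LAMB3 (1.02) and SLC7A5 (0.75). The basal list had a median of 0.62 and 5 higher members of 28, COL17A1 (0.88) and KRT19 among them (camera adjusted p = 2.4e-06; adjusted p = 0.162 with an estimated correlation), and a mean of 1.27 that rests on the KRT19 fold. The nuclear noncoding list had a median of 0.71 (camera adjusted p = 2.7e-04; adjusted p = 0.162 with an estimated correlation), led by NEAT1 (2.95±0.28, adjusted p = 3.9e-06) and MALAT1 (1.52±0.20, 4.1e-04). Over the list alone 26 ER-list, 10 basal and 4 nuclear genes were higher. Ribosomal protein mRNAs stayed near the Cytosol level, with a median of 0.06 and 0 of 77 called (camera adjusted p = 0.0545). By edgeR's quasi-likelihood test 77 genes were higher and 2 lower in IgG, all 79 in the same direction in the 3 lines. The largest folds were in KCNK10 (4.52±0.69), ITGA11 (4.39±0.28, adjusted p = 4.1e-08), KCNJ10 (4.36±0.35), the neural transcription factor NR2E1 (4.34±0.37), GFRA1 (4.32±0.35), TMEM178B (4.31±0.87), PRDM6 (4.31±0.26), RUNX1T1 (4.29±0.30) and the neural splicing factor SRRM4 (4.28±0.36). All of these but TMEM178B belong to the set of 33 genes named for IP over Cytosol, whose reads may come from a shared source, as set out below. KRT19 was at 1457, 35.3 and 1922 CPM in IgG of WT, S34F and FS. CDC42 (-1.43±0.32, adjusted p = 0.0486) and the pentose phosphate enzyme TALDO1 (-1.22±0.25, 0.0275) were lower. U2AF1 (-1.437±0.62, adjusted p = 0.617), U2AF2 (-0.06±0.25, 0.977), NPM1 (-0.29±0.21, 0.814), GAPDH (-0.21±0.11, 0.716) and ACTB (-0.28±0.12, 0.613) were not called. Median, mean and test differed in sign for mesenchymal (0.37, -0.04, up), upstream-ORF (-0.08, 0.03, up), p53 (-0.06, -0.14, up) and inflammatory genes (-0.02, -0.47, up). DESeq2 called 200 higher and 23 lower, the fit without the block 60 higher and 0 lower, leaving out S34F raised the higher count to 136, and 0 genes were lower without WT or without FS.

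**Figure D1:**
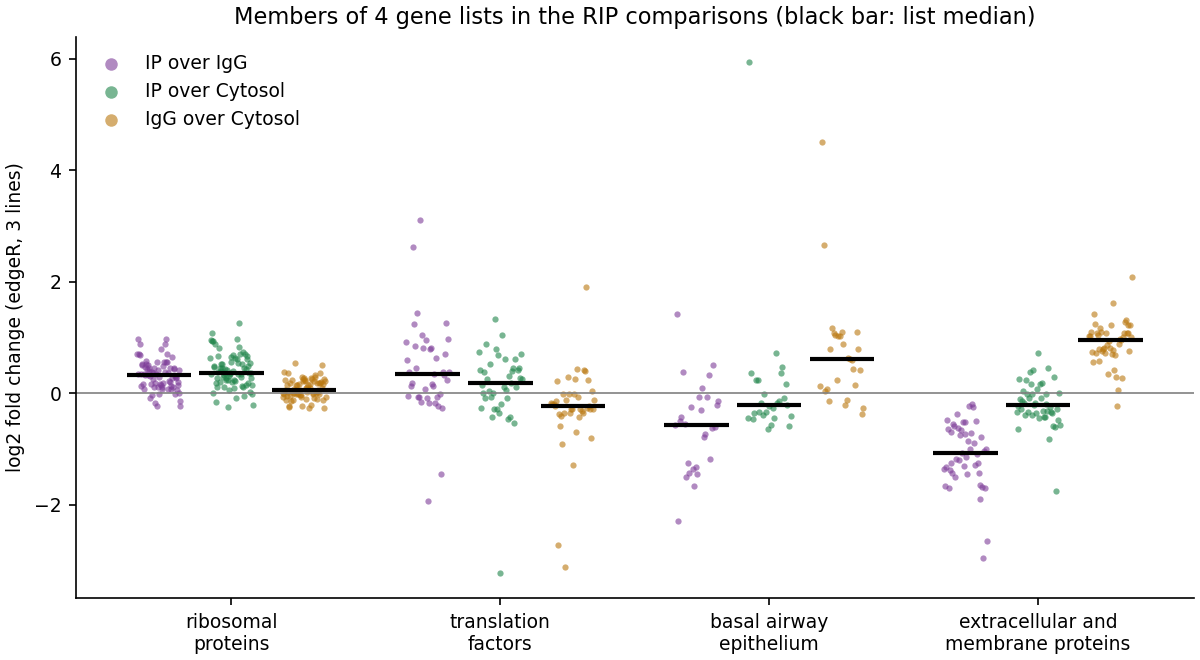
Log2 fold changes of the members of 4 gene lists in the 3 RIP comparisons, each point a gene and each black bar the list median. ER-list medians were -1.08 for IP against IgG and 0.95 for IgG against Cytosol, and KRT19, listed at 0 in Cytosol, is not drawn.

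All 31 proteasome mRNAs were higher in the 8-10 fraction than in monosomes, with a median of 1.85 log2 and PSMD2, a scaffold subunit of the regulatory particle base, at 2.44. RPS2 fell by 2.68±0.36, with RPSA at -2.53 and RPLP0 at -2.47. RPPH1, the RNA of RNase P, fell by 5.401±0.52 and RMRP, the RNA of RNase MRP, by 5.26±0.65 (adjusted p = 7.7e-06). edgeR's quasi-likelihood test called 4519 genes higher and 3439 lower among 15945, 3615 and 3088 at least 2-fold, and 7801 of 7958 kept their direction in all lines. The highest were the RNA-binding protein HNRNPD (3.32±0.36, adjusted p = 1.7e-06), EHBP1L1 (3.13±0.33), the chaperone activator AHSA1 (3.09±0.46), the dynein light chain DYNLL2 (3.07±0.39), PACSIN3 (2.98±0.40), the ESCRT subunit CHMP4B (2.96±0.35), the complex I subunit NDUFA12 (2.96±0.47), the lysosomal protease CTSL (2.96±0.40) and PSMA3 (2.89±0.44). The lowest were the lysosomal enzyme IDS (-3.99±0.33, adjusted p = 9.4e-08), FRS3 (-3.82±0.44), the phospholipase PLCG2 (-3.71±0.40), the ion channel HCN2 (-3.68±0.45) and ANKRD9 (-3.62±0.44). TPI1P3 (2.89±0.52), SCARNA6 (-3.79±0.80) and SCARNA5 (-3.63±0.75) share reads with a parent or host gene, and FAM53B-AS1, antisense to a gene, was listed at 0 in the 3 8-10 libraries and at 48.2, 63.4 and 56.2 CPM in monosomes of WT, S34F and FS. U2AF1 (1.73±0.42, adjusted p = 0.00192), U2AF2 (1.47±0.34, 0.00122), ACTB (1.49±0.37, 0.00215) and NPM1 (1.17±0.34, 0.00713) were higher and NEAT1 was lower (-0.86±0.29, 0.0186). NPM1 was nearly equal in the WT libraries, at 398 CPM against 392 CPM, and stood at -0.046 with fractions 5 to 8-10 against 1 and 2. GAPDH (0.27±0.37, 0.556), MALAT1 (-0.04±0.44, 0.943) and CXCL8 (-0.54±0.68, 0.510) were not called.

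Of 22 lists tested in the gradients, camera called 16, of which 1 stayed with an estimated correlation. That list, the nuclear noncoding RNAs, had a median of -2.01 with 10 of 14 lower and KCNQ1OT1 at -1.91 (camera adjusted p = 3.8e-06; adjusted p = 0.00964 with an estimated correlation). Proteasome mRNAs had a camera adjusted p of 3.8e-12 (adjusted p = 0.216 with an estimated correlation). The respiratory chain had 51 of 73 higher and a median of 1.59, with COX6A1 at 2.21 (2.4e-10; adjusted p = 0.338 with an estimated correlation). The ER list had 38 of 48 higher and a median of 1.42, with SLC7A5 at 1.93 and LAMB3 at 1.34 (3.4e-11; adjusted p = 0.299 with an estimated correlation). Chaperones had 24 of 30 higher and a median of 1.41, with CALR at 1.71, P4HB at 1.32 and CANX at 1.15 (7.0e-08; adjusted p = 0.301 with an estimated correlation). Cell cycle genes had 28 of 34 higher and a median of 1.29, with CDC20 at 1.54, UBE2C at 1.444 and BIRC5 at 1.29 (9.9e-08; adjusted p = 0.183 with an estimated correlation). Cholesterol synthesis had 19 of 24 higher and a median of 1.20, with MSMO1 at 1.43 and the regulator SREBF2 at -0.88 (5.7e-06; adjusted p = 0.216 with an estimated correlation). Core splicing had 26 of 45 higher and a median of 1.14, with HNRNPC at 1.61 (3.8e-06; adjusted p = 0.301 with an estimated correlation). Glycolysis had 20 of 27 higher and a median of 1.05, with PKM at 1.13 and ENO1 at 0.97 (3.8e-06; adjusted p = 0.301 with an estimated correlation). Upstream-ORF genes had 14 of 22 higher and a median of 1.02, with DDIT4 at 1.55 and TRIB3 at 1.36, while ATF4 (-0.74) was not called (7.6e-04; adjusted p = 0.338 with an estimated correlation).

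Basal airway genes had 18 of 29 higher in the 8-10 fraction and a median of 0.91 (camera adjusted p = 7.6e-04; adjusted p = 0.338 with an estimated correlation). The exon-use list had 9 of 18 higher and a median of 0.65, with the histone variant gene H2AFY at 1.94, MED24 at 1.19 and CTNNB1 at 0.99 (0.0439; adjusted p = 0.338 with an estimated correlation). Ribosomal proteins had 40 of 78 lower and a median of -1.03, although RPL3 (-0.30) was not called (1.1e-08; adjusted p = 0.359 with an estimated correlation). The snoRNA hosts had 13 of 16 lower and a median of -1.91, with SNHG16 at -3.29, GAS5 at -2.16, ZFAS1 at -1.83 and SNHG8 at -1.45 (4.1e-06; adjusted p = 0.299 with an estimated correlation). Secretory and ciliated genes had 8 of 12 lower and a median of -1.82, with MUC4 at -2.57 (0.00488; adjusted p = 0.301 with an estimated correlation). Leukocyte and endothelial genes had 3 of 13 lower and a median of -1.57, with LYZ at -1.98 (0.0259; adjusted p = 0.338 with an estimated correlation). Over the list alone, 40 ER-list, 29 cell cycle, 28 splicing, 19 basal and 15 upstream-ORF genes were higher, and 41 ribosomal proteins and 1 leukocyte gene were lower. Translation factors were mixed (19 higher, 9 lower of 41, median 0.80, camera adjusted p = 0.184), with EEF2 at -2.19, EEF1A1 at -1.93, EEF1G at -1.50 and GNB2L1 at -1.23. The p53 (median 0.64, adjusted p = 0.184), interferon (0.42, 0.398), inflammatory (-0.55, 0.520) and squamous lists (-0.71, 0.296) were not called by camera. Single members moved all the same, as B2M at 2.32, IRF1 at -1.51, IL1A at 1.61, IL1B at 1.49, CCL5 at -2.04, SERPINB2 at 1.57 and SLPI at 1.60. The mesenchymal list had a median of -0.09 and a mean of -0.45 with an upward test (camera adjusted p = 0.938). Upper-quartile scaling moved all folds by a median of -0.343 and the higher share to 41.7% against 56.8%, the fit without the block called 2739 higher, and leaving out S34F left 1939 lower.

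**Figure D2:**
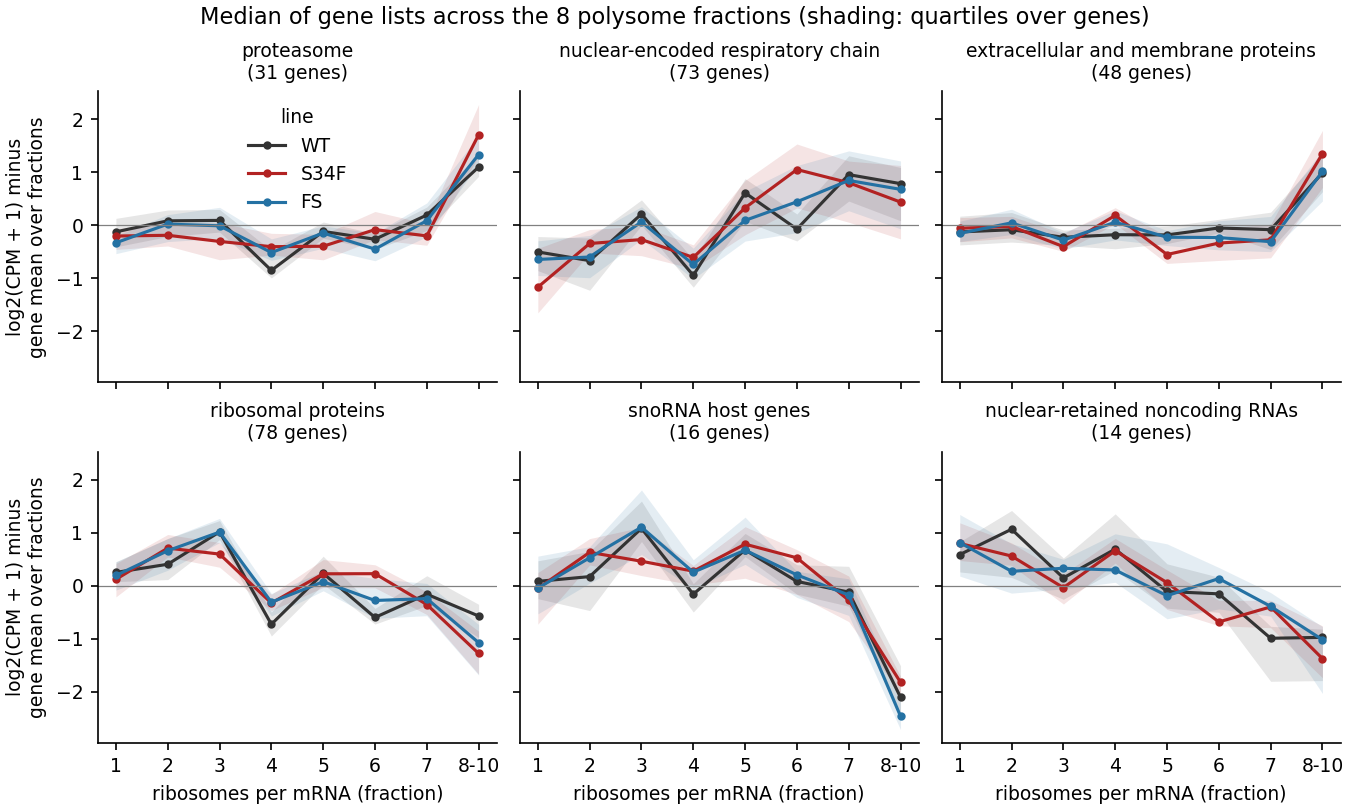
Median log2 CPM of 6 gene lists over the 8 gradient fractions of each line, as the difference from each gene's mean, with quartiles shaded. Proteasome mRNAs ended higher in the 8-10 fraction than in monosomes (median 1.85) and snoRNA hosts lower (median -1.91).

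Ribosome number per gene differed most in S34F when all 8 fractions were counted, but this rests on an 8-10 library that stood apart from its own line. Across genes with a mean count of at least 10 the S34F 8-10 library correlated at 0.728 to 0.806 with S34F fractions 1 to 7. It correlated at 0.799 to 0.879 with FS fractions 1 to 7, 0.961 with FS 8-10 and 0.897 with WT 8-10. By ribosome number, a relative index, the chaperone gene HSP90B1 stood at 5.09 in WT, 7.16 in S34F and 5.31 in FS. The clathrin heavy chain CLTC stood at 4.45, 6.06 and 4.31. KRT14, a basal keratin, stood at 5.59, 3.90 and 4.77 and NPM1 at 4.43, 5.82 and 4.58. Medians over 9504 genes were 4.76 in WT, 4.94 in S34F and 4.82 in FS, with a median counting error near 0.053 ribosomes. In S34F 1471 genes stood higher and 110 lower than both other lines, in WT 48 and 360, and in FS 119 and 29. TMM-scaled CPM turned the balance in WT to 322 and 84 and in FS to 52 and 104, and gave 900 and 196 in S34F. Without the 8-10 fraction 31 genes stood higher in S34F and 285 in FS. Higher in S34F were also the coatomer subunit COPB1 (4.08, 6.16, 4.41 in WT, S34F, FS), the ER chaperone HSPA13 (4.44, 6.82, 5.10), ZFR (4.16, 5.87, 4.21), CAND1 (4.29, 5.93, 4.11) and the tRNA synthetase EPRS (4.52, 6.12, 4.27). Lower in S34F were DICER1 (4.51, 2.90, 5.00), AGO2 (4.08, 2.77, 5.31), the Mediator subunit MED28 (5.67, 4.07, 5.49), and KRT16 (5.29, 2.71, 4.21) and KPNA2 (4.64, 3.40, 5.20), which were listed at 0 in 6 and 2 of the 24 libraries and are uncertain. The lower DICER1 number came with more, not less, CPM in the 8-10 fraction (21.9, 67.3 and 44.8 in WT, S34F and FS). WT was higher for ABCB9 (5.74, 4.83, 4.89), SEMA3B (5.57, 4.73, 4.69) and SFI1 (5.08, 4.22, 4.39), and lower for ATXN10 (3.96, 5.41, 5.26), the ribonucleotide reductase gene RRM2 (4.04, 5.38, 5.23), TMPO (4.396, 5.55, 5.43), SRP9 (4.47, 5.91, 5.49), CNN3 (4.84, 6.50, 5.78), SLC25A24 (4.79, 6.20, 5.73) and MRPL19 (5.12, 6.59, 6.18). FS was higher for ORAI3 (4.74, 4.22, 5.81) and PAF1 (5.15, 5.30, 6.08), and lower for VMP1 (3.65, 4.12, 2.73). MT1E (4.18, 5.28, 5.95), lower in WT, and PPP1R11 (5.62, 5.28, 4.06), lower in FS, were listed at 0 in 6 and 11 of the 24 libraries, so their numbers are uncertain. SCARNA5, PKD1P1, NOMO1, KRT6C, SMG1P3, TPI1P3 and MTRNR2L genes also passed, with reads that copies or host genes can share. U2AF1 stood at 5.73, 5.27 and 5.11, U2AF2 at 5.35, 5.19 and 5.61, and GAPDH at 4.56, 4.14 and 4.403. ACTB stood at 5.27, 5.15 and 5.73, MALAT1 at 4.25, 4.67 and 4.56, and NEAT1 at 4.13, 4.00 and 4.38.

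Chaperones had the largest list shift in S34F against WT, a median of 0.758 ribosomes at percentile 100 of matched random lists, with CANX at 1.19. Their estimated correlation in the gradients was 0.434, which random lists lack. Outside the central 95% of random lists lay 7 of 20 lists in S34F minus WT and 8 of 20 in FS minus WT. Cell cycle genes (0.656, percentile 99.98), the exon-use list (0.639, 99.9, with CTNNB1 at 1.33), translation factors (0.479, 100, with EEF1A1 at 0.56), proteasome (0.374, 98.98), cholesterol synthesis (0.315, 99.38, with MSMO1 at 1.33) and splicing (0.25, 98.9) also lay high. SERPINB2 (2.19) and IL1A (1.78) had ribosome numbers higher by more than 1. Without the 8-10 fraction the chaperone median was 0.011 (percentile 70.59), while respiratory chain (0.174, 100), ribosomal proteins (0.102, 99.6), cell cycle (0.111, 99.57) and translation factors (0.089, 98.94) lay high and ER (-0.151, 0.01) and basal genes (-0.135, 0.26) low. In FS against WT, basal (-0.288, percentile 0), mesenchymal (-0.335, 0) and ER genes (-0.169, 0) lay low, with KRT5 at -0.50, FN1 at -0.57 and TGFBI at -0.54, and stayed low without the 8-10 fraction (-0.164, -0.153 and -0.129). p53 targets (-0.13, 0.36) and ribosomal proteins (-0.1, 1.87) lay low as well, and cell cycle (0.288, 99.51), cholesterol (0.258, 99.92) and proteasome genes (0.269, 99.42) high, but these 5 lists were inside the central 95% of random lists without the 8-10 fraction. The median S34F minus WT difference over all genes went from 0.079 to -0.014 without the 8-10 fraction and its SD from 0.5 to 0.238, against 0.091 to 0.097 and 0.288 to 0.26 for FS minus WT. With 1 gradient per line, no test was possible.

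**Figure D3:**
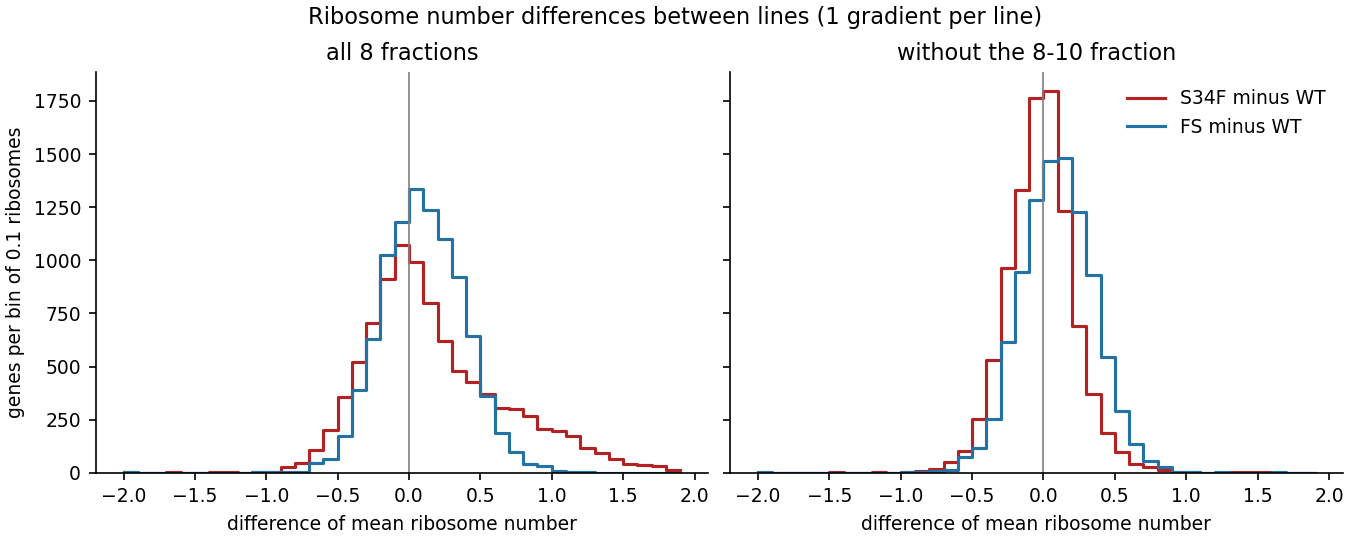
Histograms of the difference in ribosome number from WT over 9504 genes for S34F and FS, with all 8 fractions and without the 8-10 fraction; values beyond 2 are in the outer bins. The SD of the S34F difference was 0.5 with all fractions and 0.238 without 8-10.

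AEBP1, a matrix-associated transcription regulator, was higher in S34F than in WT by 5.69 log2 in Cytosol and 3.68 in the polysome mean, and in FS by 6.81 and 3.13. The aldehyde dehydrogenase ALDH2 was lower, at -5.53 and -2.92 in S34F and at -5.48 and -3.33 in FS. IL1B was lower, at -1.87 and -2.46 in S34F and at -1.22 and -2.13 in FS. S34F had 66 genes at least 2-fold higher and 80 lower than WT in both sets, FS had 230 and 122, and S34F against FS had 28 and 59. TMM-scaled CPM turned S34F against FS to 54 and 37, and a prior of 5 CPM left 37 genes higher in FS than WT. Higher in S34F than WT were ARSI (3.73, 3.16 in Cytosol and polysomes), SLC47A2 (2.71, 3.58), ZBTB16 (2.71, 2.75), TMEM25 (3.66, 2.70), RASIP1 (3.51, 2.66), the Notch modifier LFNG (2.598, 2.84) and IMPA2 (2.82, 2.27). Lower were the protocadherin PCDH10 (-3.04, -3.06), the cotransporter SLC12A7 (-3.93, -2.94), G0S2 (-2.76, -2.74), the neurotensin receptor NTSR1 (-3.65, -2.59), SLC9B2 (-2.98, -2.59), STAC (-2.38, -2.66) and the transglutaminase TGM2 (-4.81, -2.01). Higher in FS than WT were GRB10 (3.01, 3.53), ARSI (3.34, 2.75), TMEM25 (3.49, 2.74), SDK2 (3.63, 2.597), RASIP1 (3.75, 2.37), and the proteases PRSS8 (2.25, 2.18) and PRSS12 (4.10, 2.17). Lower in FS were EMC10 (-5.45, -5.54), JOSD2 (-6.64, -5.25), PCDH10 (-3.51, -3.11), SLC12A7 (-3.98, -3.01), RAB39B (-2.78, -2.96), SMOX (-2.76, -3.30) and SLC9B2 (-2.94, -2.65). NTSR1, PRSS8 and JOSD2 were each listed at 0 in 1 library and are uncertain. U2AF1 was at -1.29 and -0.74 in S34F and at 0.02 and 0.32 in FS. Across genes, which are not independent replicates, Cytosol and polysome differences correlated at r = 0.299 for S34F against WT, 0.245 for FS against WT and 0.014 for S34F against FS.

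In Cytosol, inflammatory genes had a median of -0.912 in S34F against WT (percentile 0 of random lists) and -0.153 (15.63) in FS. p53 targets were higher at 0.647 (100) and 0.421 (99.99), with CDKN1A at 0.98 and 0.32, and ribosomal proteins at 0.361 (100) and 0.111 (100). Translation factors (0.221, 99.56) were higher and glycolysis genes (-0.306, 1.01) lower in S34F Cytosol. In FS Cytosol cell cycle genes (0.54, 100), nuclear noncoding RNAs (0.454, 99.7) and ER genes (0.073, 99.12) were higher. In the polysome mean, cell cycle genes were higher in S34F (0.894, 100) and FS (1.096, 100) and inflammatory genes lower (-1.197, 0 and -0.483, 0.01), while FS had higher translation factors (0.738, 100) and lower snoRNA hosts (-0.712, 0). In S34F Cytosol cell cycle genes were inside the central 95% of random lists. Outside it lay 14 of 21 lists in the S34F polysome mean and 11 of 21 in that of FS, against 6 and 8 of 21 in Cytosol. KRT5 was higher in S34F Cytosol (1.17) than in FS Cytosol (0.35), both against WT. The secretory marker MUC5B was at -2.98 and -2.89 and the G protein gene GNAS at -3.78 and -3.25 in Cytosol of S34F and FS against WT.

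U2AF1 IP enrichment over Cytosol had a S34F minus WT median of -0.207 over all genes. NPM1, a nucleolar chaperone, had a log2 IP over Cytosol of 0.80 in WT, 0.10 in S34F and 0.39 in FS, though with 1 library per line this was not tested. U2AF1 mRNA had a S34F minus WT difference of -1.68 with 13 counts in S34F IP, and its IgG over Cytosol was as much lower, at -0.093 in WT and -2.069 in S34F. Ribosomal proteins had a S34F minus WT median of -0.146, which was not below that of all genes but low against matched genes (percentile 0), and a S34F minus FS median of -0.193 (0), the only list outside the central 95% of random lists in those differences. In FS against WT mesenchymal (-0.424, percentile 2.16) and cholesterol genes (-0.331, 2.25) lay low. CYC1, METRN, MRPL53, MCAT, FAM173A and SNRNP25 were listed at 0 in WT IP and MAPK7 and TMEM14B at 0 in S34F IP, so their differences have no defined size. The highest others in S34F minus WT were ATN1 (6.70) and DTX2 (6.46, with 2 counts in WT IP). The lowest were BAHD1 (-4.38), CCNDBP1 (-4.36), PHLDB2 (-4.34), PAQR4 (-4.34), REXO2 (-4.27) and RAI14 (-4.15), with at most 7 counts in S34F IP. U2AF2 (0.48), GAPDH (-0.01), ACTB (0.29), MALAT1 (-0.51) and NEAT1 (-0.59) differed less. Among 9227 genes 942 were 2-fold higher and 2381 lower in S34F than WT, but IgG over Cytosol gave 2107 and 1980 with an SD over genes of 1.57 against 1.504. FS against WT gave 1119 and 1916 (IgG 2079 and 2123), and S34F against FS 1586 and 2205 (IgG 1878 and 1637, with an SD of 1.432 against 1.608 for IP). Across 8118 genes, which are not independent replicates, the S34F minus WT differences in IP enrichment and ribosome number had a Spearman correlation of -0.215, and of -0.004 with IP over IgG in 6170 genes. For FS minus WT it was -0.041 and 0.039, and for S34F minus FS -0.1 and -0.043.

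In Flp-In-293 cells, most U2AF1 clusters lay in coding regions, introns and 3-prime UTRs in cytoplasm, and in coding regions, introns and intron-to-exon junctions in chromatin. The U5 RNA gene RNU5D-1 had the most cluster reads in cytoplasm, 21651 with WT and 22895 with S34F protein. Apart from the copies named below, MORF4L1 (4057, and 6150 in S34F) and ATAD5 (1637) followed in WT. Of the MORF4L1 reads, 3961 and 6051 lay in 1 cluster annotated as other noncoding RNA, so they are not shown to come from its mRNA. In S34F cytoplasm the U2 gene RNU2-2P had 3743 reads, MALAT1 4035 and FCGR2B 5697 in an intron. RNA5SP44 (3389), RNA5SP84 (1370), RN7SL634P (1549), RN7SL49P (1385) and RNY4P17 (1448) in WT and RNA5SP477 (8436), RN7SL559P (8219) and RN7SL634P (5289) in S34F are copies whose reads cannot be placed with certainty. In chromatin the leading genes were the kinase PRKDC (26052 reads in 209 clusters), RNA28S5 (18071), IARS (15408), the splicing factor RBM39 (14042), UBR4 (13507), the helicase DDX17 (13083), POLA1 (13072) and HNRNPH1 (12651). The lists held 26613 clusters in 7569 genes for WT cytoplasm, 28828 in 6918 for S34F cytoplasm and 92895 in 9481 for chromatin. Intron-to-exon junctions held 17.8% (17.6 to 18.1) of chromatin clusters, 2.8% (2.61 to 3.01) of WT and 3.42% (3.22 to 3.64) of S34F cytoplasm clusters. The 5-prime UTR held 3.54% (3.32 to 3.76) in WT cytoplasm, 2.37% (2.20 to 2.55) in S34F cytoplasm and 1.13% (1.06 to 1.20) in chromatin. Coding regions held 32.5%, 26.5% and 32.6%, introns 28.9%, 34.2% and 29.77%, 3-prime UTRs 15.1%, 17.3% and 5.82%, and start codons 1.23%, 1.11% and 0.98% in that order. NPM1 had 2 clusters and 65 reads in WT cytoplasm, 53 of them in a 70 nt cluster of the 5-prime UTR (chromosome 5, 170814864 to 170814933, plus strand as in the list, genome build not stated). The T-to-C fraction of this cluster was 0.269, below the lower quartile of the WT cytoplasm list (0.542, with a median of 0.837). With S34F protein NPM1 had 10 clusters and 97 reads with none in the 5-prime UTR, and in chromatin 18 clusters and 854 reads. GAPDH had 51, 105 and 248 reads in WT cytoplasm, S34F cytoplasm and chromatin, ACTB 227, 129 and 0, U2AF2 291, 138 and 1052, and CXCL8 had no cluster. WT and S34F cytoplasm shared 10.2% of WT clusters (2.40% after a shift of 500 nt), and 18.2% of WT cytoplasm clusters met a chromatin cluster (shifted 4.94%) as did 21.3% of S34F cytoplasm clusters (shifted 5.28%). WT cytoplasm clusters that met chromatin clusters lay at junctions in 8.72% and in coding regions in 54.6%, against 1.49% and 27.6% of the others.

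**Figure D4:**
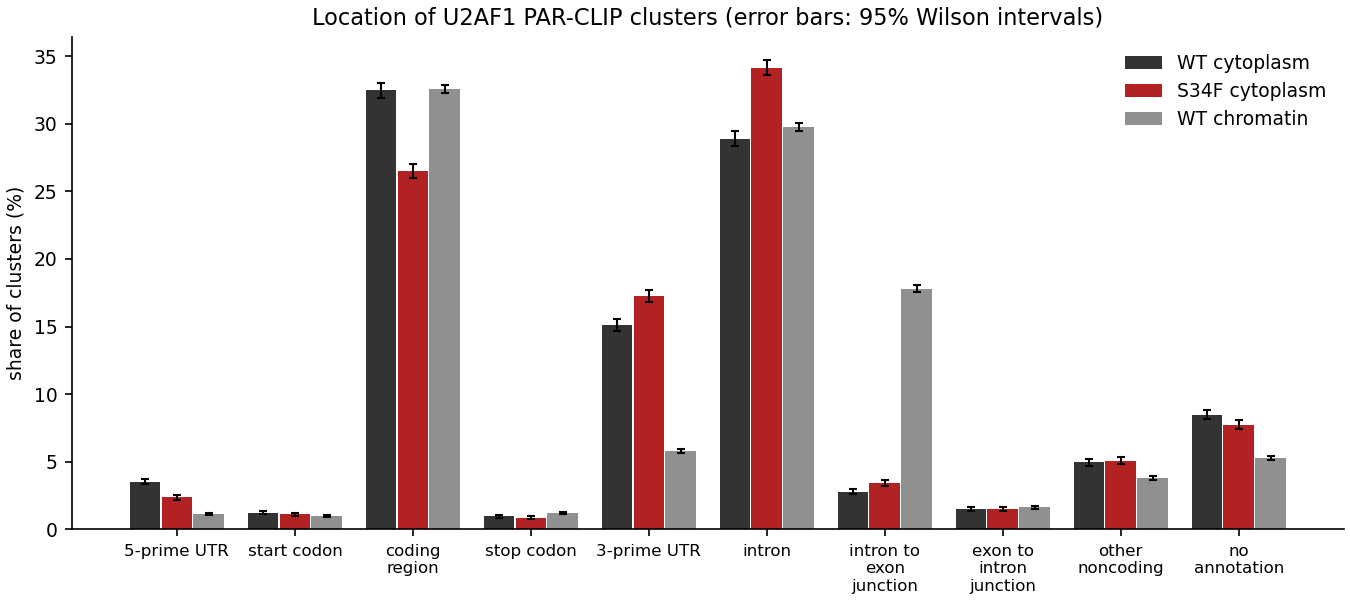
Share of PAR-CLIP clusters by place in the gene for the 3 lists, in percent, with Wilson 95% intervals for counting error. Intron-to-exon junctions made up 17.8% of chromatin clusters and 2.8% and 3.42% of WT and S34F cytoplasm clusters.

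Genes bound in both cytoplasm lists were higher in IP than matched genes. For lists not limited to a region, a cluster at any place made a gene count as bound. Introns held 28.9% of WT and 34.2% of S34F cytoplasm clusters, so binding to mature mRNA is not shown for each gene. The 4594 measured genes bound in both cytoplasm lists had a median IP over IgG of 0.138 log2 and IP over Cytosol of 0.036, both at percentile 100. Genes with a 5-prime UTR cluster stood at 0.175 (100) and 0.098 (100), those with a 3-prime UTR cluster at 0.171 (100) and 0.051 (100), and those with a coding cluster at 0.087 (100) and -0.035 (99.97). Genes bound only with S34F protein stood at 0.171 (99.98) and 0.018 (97.84), those bound only with WT protein at -0.036 (6.4) and -0.166 (0), or 0.039 (98.54) and -0.101 (24.53) with clusters of at least 20 reads, and those bound only in chromatin at -0.091 (0) and -0.149 (0.01), or 0.068 (97.52) and -0.048 (59.14) with that threshold. That threshold also changed the lists, since genes with only smaller cytoplasm clusters then counted as not bound there. Chromatin-only genes went from 2154 to 5024 and WT-only genes from 2304 to 1471, so the values with and without it compare different gene sets. Of the 26 genes called higher in IP than IgG, 25 had a S34F cytoplasm cluster (96.2%, 81.1 to 99.3, against 30.8% to 69.2% in 95% of random lists of matched genes) and 24 a chromatin cluster (92.3% against 46.2% to 84.6%). The 19 with a WT cytoplasm cluster (73.1%) were within the random range of 42.3% to 76.9%. Of the 130 lower, 36 had a S34F cytoplasm cluster (27.7% against 43.1% to 60%) and 52 a WT one (40.0% against 52.3% to 67.7%), while 75 in chromatin (57.7%) were at the edge of the random range of 57.7% to 73.1%. Ribosome number in S34F minus WT had a median of 0.288 for genes bound in both cytoplasm lists and 0.3 for genes with a 5-prime UTR cluster, both at percentile 100, against -0.012 (0) for genes bound with WT protein only. Without the 8-10 fraction the first pair turned to -0.042 (0) and -0.031 (1.24), and the WT-only genes went to percentile 100 with clusters of at least 20 reads. In FS minus WT the same pair stood at 0.121 (100) and 0.091 (92.09), and at 0.133 (100) and 0.125 (100) without that fraction. The lists come from another cell type than the RIP and gradients.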

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

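The search for lists at opposite ends of the random lists was chosen only after the list medians had been seen, and differences between lines were not tested. Of 83 list medians compared between S34F minus WT and FS minus WT, 3 lay in opposite tails. Ribosomal proteins had a median IP over Cytosol difference of -0.146 in S34F minus WT and 0.095 in FS minus WT. Cholesterol synthesis genes had a median RNA level difference in Cytosol of -0.322 in S34F and 0.357 in FS. Nuclear-encoded respiratory chain genes had a median RNA level difference in the polysome fractions of 0.186 in S34F and -0.292 in FS.

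Some data could not be used by gene. Gene names turned into dates held 0.143% of all polysome counts, and clusters without an annotation made up 8.49% of the WT cytoplasm, 7.74% of the S34F cytoplasm and 5.28% of the WT chromatin list.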

How the results depend on the processing

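The fits without genes that had isolated zeros, the cluster threshold of 3 conversion positions, and the lists and targets without the 8-10 fraction were chosen only after results were seen; all other alternatives were planned. Of 1506 alternative values, 1112 stayed the same, 268 moved, 104 were weaker, 5 stronger and 17 reversed. Values of comparisons stayed the same in 138 cases and moved in 112, and those of single genes, lists or sites stayed in 974, moved in 156, weakened in 104, strengthened in 5 and reversed in 17. The planned minimum of 2 conversion positions removed no cluster. Each comparison had 10 splits of its 6 libraries, too few for a share under 0.05. With line left out of the model, the real split ranked 1 each time, with 32 genes against at most 2 in other splits for IP against IgG, 34 against 6 for IP against Cytosol, 50 against 5 for IgG against Cytosol and 6251 against 1 for 8-10 against monosomes.

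Without the line block, IP against IgG had 0 higher and 32 lower genes, IP against Cytosol 36 and 0, IgG against Cytosol 0 lower and 8-10 against monosomes 2739 higher, and that block moved no other count by more than 1.5 times. It weakened 26 of the single-gene results, left 70 the same and reversed 0. Leaving out 1 line at a time gave 2 to 20 higher and 15 to 187 lower genes for IP against IgG, 1 to 7 lower for IP against Cytosol, 62 to 136 higher and 0 to 3 lower for IgG against Cytosol, and 1939 to 2735 lower for 8-10 against monosomes. DESeq2 gave 226 higher and 441 lower for IP against IgG, 115 and 52 for IP against Cytosol and 200 and 23 for IgG against Cytosol. The 3 comparisons without a filter gave 71 and 281, 110 and 43, and 190 and 7. Only the libraries compared gave 28 lower for IP against Cytosol and 1 lower for IgG against Cytosol, and the 2-fold threshold gave 13 higher for IP against IgG. Without isolated zeros, IP against IgG had 44 higher and 204 lower genes and IP against Cytosol 14 lower. With an estimated correlation camera called 0, 0, 0 and 1 lists in the 4 tested comparisons, against 4, 6, 3 and 16. NPM1 reversed to -0.046 with fractions 5 to 8-10 against 1 and 2. The causes were not tested.

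For ribosome number, TMM-scaled CPM gave 322 higher and 84 lower genes in WT, 900 and 196 in S34F, and 52 and 104 in FS. The log2 ratio of fractions gave 4 and 9, 99 and 18, and 26 and 11. A minimum of 2000 counts gave 23 and 92, 441 and 70, and 54 and 15, and 200 counts gave 599 lower in WT and 201 higher and 58 lower in FS. With the last fraction counted as 10, WT had 95 higher and S34F 190 lower, and counted as 8, WT had 29 higher and S34F 56 lower. No monosome fraction gave 675 higher in FS. No 8-10 fraction gave 19 higher and 60 lower in WT, 31 higher in S34F and 285 higher in FS, reversed MRPL19 to 0.051, and left 3 lists outside the central 95% in FS minus WT and 2 in S34F minus FS. Without that fraction, target percentiles reversed to 0 and 0 in S34F minus WT and S34F minus FS for genes bound in both cytoplasm lists, 1.24 and 0 for 5-prime UTR, 0 and 0 for coding and 0.01 and 0 for 3-prime UTR clusters, and in S34F minus FS to 100 for WT only and 100 for chromatin only. With at least 20 reads, targets reversed to 97.52 for chromatin only in IP over IgG, to 100 and 100 for WT only and to 100 and 99.95 for chromatin only in S34F minus WT and S34F minus FS. That threshold also changed which genes each list held, so these reversals compare different gene sets.

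For RNA level, 200 counts gave 35 higher and 53 lower genes for S34F against WT, 148 and 81 for FS against WT, and 16 and 38 for S34F against FS. A prior of 5 CPM gave 31 and 51 for S34F against WT, 37 higher for FS against WT, and 12 and 12 for S34F against FS, which TMM-scaled CPM moved to 54 and 37. For IP enrichment, 200 counts gave 401 and 985 for S34F minus WT, 444 and 772 for FS minus WT, and 695 and 960 for S34F minus FS. The relation of IP enrichment with ribosome number was -0.004, 0.039 and -0.043 with IP over IgG for S34F minus WT, FS minus WT and S34F minus FS, and -0.241 and -0.138 with 2000 counts for the first and last. For cluster overlaps, at least 20 reads gave 13.94% of WT cytoplasm clusters with S34F, 15.95% of S34F with WT, 26.66% of WT and 32.7% of S34F with chromatin, and 2.4% of chromatin with WT, and junction shares of 4.19% in S34F and 22.13% in chromatin. At least 3 conversion positions gave 13.42% of WT with S34F, 20.8% of WT with chromatin, 4.47% of chromatin with WT, and junction shares of 3.75%, 4.44% and 26.11% in WT cytoplasm, S34F cytoplasm and chromatin. An overlap over 50% of both clusters gave 7.5%, 6.93%, 10.33%, 12.64% and 2.96% in the order of the overlaps with 20 reads.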

Other observations

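The tests of nuclear RNA, of the ER list and of ribosomal proteins in IgG were chosen only after results were seen, and the other tests below were written before. JOSD2, a deubiquitinase gene listed at 0 in 1 polysome library, and EMC10, a subunit of the ER membrane insertase, were higher in S34F than in FS by 5.703 and 4.88 log2 in Cytosol and 4.36 and 4.09 in polysomes. GRB10 (-1.89, -2.13), CTGF (-1.80, -1.87) and PPARG (-1.70, -1.63) were lower. U2AF1 RNA carried 9 clusters with 264 reads in WT cytoplasm, 19 with 392 in S34F cytoplasm and 29 with 2303 in chromatin. NEAT1 carried 29 clusters with 850 reads, 33 with 1585 and 115 with 10099.

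A set of 33 genes lay at a near-constant height over Cytosol, with a median of 4.22 log2 in IgG (3.19 to 4.52) and 3.09 in IP (2.23 to 3.32). In the polysome libraries, which did not choose them, the 24 measured members had a residual SD of 0.449 log2, against 0.578 for the lowest of 1000 matched random sets. This is consistent with reads of 1 shared source counted under many gene names. Nuclear RNA in the precipitates might add to it, since NEAT1 rose by 2.946 in IgG over Cytosol, within its error of the lowest member (3.19), while MALAT1 at 1.515 lay far below, so the 2 cannot be told apart because the RNAs disagree.

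ER-list mRNAs were lower in IP than in IgG, and pull-down of these mRNAs by IgG may account for this, since their median in IgG over Cytosol was 0.952 (0.793 to 1.039). Both comparisons share the 3 IgG libraries, so their folds are not independent. IP over Cytosol, which uses no IgG library, had a median of -0.22. The interval treats members as independent, although their estimated correlation was 0.457. Transcript length was not a likely source, as the median was -1.196 (-1.424 to -0.945) after a trend on length was removed. The higher ribosomal protein mRNAs could have had the same source, but their median in IgG over Cytosol was 0.063 (0.012 to 0.152).

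The excess of the 1471 genes with higher ribosome numbers in S34F lay in the 8-10 fraction, with 36.5% of their CPM there in S34F and 15.8% in WT and in FS, as its median went from 0.89 to -0.151 (-0.162 to -0.133) without that fraction and 22 of them still passed. The S34F 8-10 library had a correlation of 0.681 with fraction 7 of S34F over genes with a mean count of at least 50, against 0.886 in WT and 0.82 in FS, and over genes with at least 10 higher correlations with FS fractions (0.799 to 0.879) than with its own (0.728 to 0.806). In a check chosen after results were seen, only 4 genes told S34F from FS by 4-fold in Cytosol and fractions 1 to 7. In the S34F 8-10 library 3 of them were nearer S34F, with a median position of 0.941 (0 at FS, 1 at S34F). Of 22 genes that told S34F from WT, 19 were nearer S34F there. The 4 genes are too few to say whose RNA the library holds. The S34F 8-10 library correlated at 0.897 with that of WT, above its correlations with S34F fractions 1 to 7. Real loading on 8 to 10 ribosomes could lower correlations with lighter fractions as well. It and a property of this library cannot be told apart with 1 gradient per line. Transcript length, with a weak Spearman correlation of 0.139 across genes, and U2AF1 binding, with bound genes at percentile 100 but 0 without the 8-10 fraction, may take part and stay open. Bound genes also lay at percentile 100 in FS minus WT, with (0.121) and without (0.133) that fraction, so a higher rank over WT was not confined to S34F. In S34F minus FS these genes stood at 0.165 (percentile 100) with all 8 fractions and at -0.176 (percentile 0) without the 8-10 fraction.

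A sequence preference of the S34F protein could show as a different base before AG at junction clusters. Only junction clusters with 1 AG were used, 250 of 986 in S34F cytoplasm and 202 of 746 in WT cytoplasm. That this AG is the one of the splice site is not shown. T preceded AG in 20.8% (16.2 to 26.3) of these S34F clusters and 27.2% (21.6 to 33.8) of these WT clusters. With so few clusters and overlapping intervals, a preference cannot be told apart from equal use. In WT chromatin T preceded AG in 37.9% (36.3 to 39.6) of 3423 such clusters.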
